A study of Mus musculus with 14 samples.

How the data were processed

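Cy3-labelled RNA of undifferentiated mouse ES cells and of cells on days 1 to 6 of monolayer culture in N2B27 was hybridised, per the labels, against Cy5-labelled Universal Mouse Reference RNA on 60-mer Agilent arrays. There were 14 arrays, 2 for each of 7 groups, with no dye swap, so a dye effect specific to a probe stays in each ratio and leaves the contrasts between groups only if it was equal on all arrays. The groups were taken from the sample titles, which the descriptions and treatment protocols match. The source names of 8 samples speak of brain samples instead, and they were not used. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

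Each scanner file holds an intensity for every spot and channel, made by the authors with Agilent Feature Extraction A.7.1.1, per the file headers. The raw mean foreground and median background intensities were used. The same files hold a log10 ratio of Cy5 over Cy3 after Agilent's background subtraction and dye normalization, per the file headers, and its sign was turned for use as an alternative. Other columns, also deposited, are spot flags for outliers, saturation and signal over background. The series matrix holds the authors' values on a log10 scale. Its scaling is stated nowhere in the sources used here. Set against the scanner files, its columns followed the turned log10 ratio plus an offset per probe whose SD over arrays was under 0.001 for 88.5% of probes, and for 89.9% of probes the offset lay within 0.001 of the mean log10 Cy5 signal. Column medians were 3.01 to 3.02, and what was done to the remaining probes stays unknown.

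Background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with the 1080 control spots at weight 0, using limma 3.58.1 in R 4.3.3. Loess takes most genes as unchanged on balance, so a shift of all genes would not be seen. The offset shrinks the ratios of dim probes. Spots with an outlier flag in either channel were set missing, 3 to 92 per array, and saturated spots, 19 to 84 per array in Cy3 and 55 to 92 in Cy5, were kept. Of 21052 probes, 20667 were well above background in Cy3 on both arrays of at least 1 group, and 385 were not tested. Probe accessions were matched, without versions, to a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names only. Of the probes, 10422 were named by accession, 44 by a synonym and 10586 not at all. Unnamed probes were counted and not named. Of 240 genes with several tested probes, the brightest on average stood for the gene. At day 6 all probes were called for 49 of them, some for 92, and in opposite directions for 7. This left 20395 features. The array design's own annotation is not given in the sources used here.

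Groups were compared with lmFit and eBayes on all 14 arrays, as contrasts of group means with the spread pooled over groups (7 residual and 4.44 prior degrees of freedom). Benjamini-Hochberg adjusted p under 0.05 made a call. The contrasts were each day against ES, each day against the day before, an F test over the 6 days, and the transient rule, which needs days 2 and 3 above both ES and days 5 and 6. A total of 31 gene lists with at least 5 measured members were tested with camera, two-sided, at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists of a day. They cover pluripotency, neural, patterning, signalling, metabolic and other cell type genes. Camera used only members with no missing spot on the arrays fitted, for cholesterol synthesis 12 of 15 measured genes. Its p-values can therefore rest on fewer genes than the member counts beside them. Counts adjusted over the list alone are given with the lists described for each day.

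The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took, among called genes whose 2 arrays lay on the same side of both ES arrays, the 10 largest rises and falls at day 6, 5 of each on days 1 to 5, 3 of each per daily step, and the 10 leading transient genes. It added the 4 largest called members of each list and a fixed set of markers. This gave 183 named genes, some of which are not reported here. Genes of that set without a named probe are given as not named here. Where a group had no array well above background, or was saturated on all, a bound on the fold of the Cy3 signal is given. The fold of the fitted ratio stands beside it.

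The file headers show 2 extraction sessions, which follow the replicate numbers in all 7 groups, so the fit with the replicate number as a block is also the fit with the session as a block. It is given beside each count of features. Because groups are balanced over sessions, the block leaves a gene's log2 change as it was unless a spot is missing. The scripts were tested on simulated data made from the 20395 features of the day 6 comparison. Of changes of 0.5, 1 and 2 on the log2 scale, 82.1%, 98.5% and 98.5% were recovered, and of 212 calls 14 were members of the list that had been shifted in the simulation and 12 had no simulated change. In the transient comparison 85.1%, 100% and 100% were recovered. The simulated day 5 comparison, with no change, gave 0 calls, and the shifted gene list was found with 0 others. The simulated noise was independent between features and held no session effect. These counts therefore do not measure false calls that correlated genes or sessions could give.

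The alternatives were no background subtraction, Agilent's processed ratios, Aquantile after loess, median centring, no filter and a strict filter on dim probes, the series matrix, every probe as a row, the replicate block, a trended robust variance, a fit on only the groups compared, an estimated correlation, and each array left out. The Cy3 channel alone, quantile normalized, was added after seeing the data.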

Results

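Gene expression was measured in mouse embryonic stem (ES) cells, the pluripotent cells of the early embryo kept in culture, and on days 1 to 6 of their conversion towards neural fate. The undifferentiated cells had been kept on gelatin in ES medium with leukaemia inhibitory factor (LIF), the cytokine that sustains self-renewal. The cells of days 1 to 6 had been plated on gelatin as a monolayer in N2B27, a defined neural medium. Each of the 7 groups had 2 arrays, 14 in all. Each array carried sample RNA in the Cy3 channel and a reference RNA, pooled from mouse cell lines, in the Cy5 channel, so every value is a log2 ratio of sample to reference. Between 95.8% and 98.9% of probes per array were well above background in Cy3, and the median background-subtracted Cy3 signal ran from 174 to 380. The number of arrays limits the precision.

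Replicate arrays correlated at r = 0.966 to 0.986 across features, which are not independent replicates, and the lowest correlation between any 2 arrays was 0.659. The tested set held 20395 features, of which 10073 were named genes and 10322 were probes without a gene name here. Replicate 1 of every group was extracted from its scan in session 1 and replicate 2 in session 2, so each session held all 7 groups. Of the 7200 features called at day 6 and measured in both sessions, all 7200 changed the same way in both, a rule that 2 arrays per group make easy to meet.

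**Figure D1:**
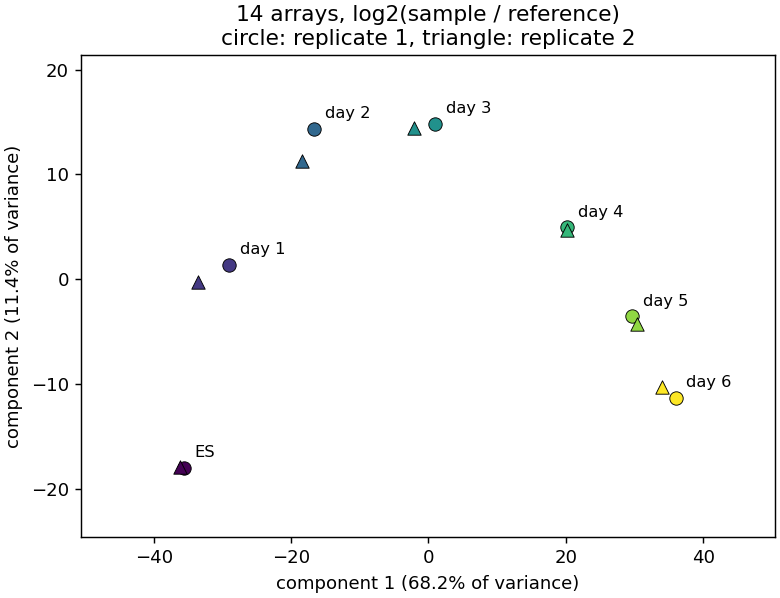
Each point is an array placed by principal components 1 and 2 of the log2 ratios (20056 features measured on all arrays), with circles for replicate 1 and triangles for replicate 2. Component 1 holds 68.2% of the variance and runs from ES (-35.6 and -36.1) to day 6 (36.0 and 34.0), and component 2 holds 11.4%.

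The course as a whole asked which genes change as ES cells leave pluripotency for the neural lineage. Markers of the ES state such as Zfp42 and Klf4 were lower and markers of neural progenitors such as Hes5 and Fabp7 were higher by day 6. Over the 6 contrasts of a day with ES, limma's moderated F test called 7103 features (34.8% of 20392), 4304 of them named genes. The largest difference from ES fell on day 6 for 3643 of these (51.3%), on day 5 for 1399, on day 4 for 801, on day 3 for 494, on day 2 for 356 and on day 1 for 410. The count was 8275 with extraction session as a block and 4398 from the Cy3 channel alone, an alternative chosen after seeing the data.

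At day 6, 10 named genes led the rise over ES. Values after a gene name are log2 changes ± SE of the fitted contrast, with n = 2 arrays in each group. Insl6, of the insulin and relaxin family of peptides, rose 31.8-fold (4.99 ± 0.24, adjusted p = 2.96e-08), and Crabp1, a cytosolic retinoic acid binding protein, rose 25.7-fold (4.68 ± 0.18). The homeobox gene Meis2 rose 24.2-fold and Rgs2, a regulator of G protein signalling, 21.3-fold. Nr2f1, an orphan nuclear receptor of neural development, rose 21.0-fold, and Irx3, a homeobox gene of the caudal neural plate, 19.9-fold. Hes5, an effector of Notch signalling in neural progenitors, rose 19.4-fold, and Zfp521, a zinc finger gene that promotes neural fate in ES cells, 17.6-fold. Zic1, of the dorsal neural tube, rose 17.5-fold and Fabp7, a fatty acid binding protein of radial glia, 16.9-fold.

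The 10 named genes with the largest falls at day 6 included several that mark ES cells. Tdgf1, the Nodal co-receptor Cripto, fell 34.9-fold (-5.13 ± 0.25, adjusted p = 2.87e-08); its Cy5 signal fell too, by 2.38 on the log2 scale, so that the ratio fell less than the Cy3 signal (-7.13). The strict filter on dim probes dropped the Tdgf1 probe used here, and another probe, which then stood for the gene, was at -2.53. Morc1, a germ cell gene, was not well above background on days 4 to 6. At day 6 it was 32.5-fold lower than in ES in the fitted ratio (adjusted p = 5.96e-11). Its Cy3 signal was at least 38.6-fold lower. Such bounds are not ratios to the reference but compare means of Cy3 values after loess and Aquantile, with no dye swap to balance the dyes. Zfp42 (Rex1), a marker of undifferentiated ES cells, fell 26.8-fold, the transcription factor gene Klf2 19.8-fold and the ribosomal protein gene Rpl39l 19.5-fold. Dppa3 fell 18.2-fold, and Tdh, the threonine dehydrogenase on which mouse ES cells depend, fell 15.9-fold. Nr0b1 (Dax1) fell 15.6-fold, Upp1, a uridine phosphorylase, 14.4-fold, and Spp1, which encodes osteopontin, 14.3-fold.

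In all, 7246 of 20394 features (35.5%) were called at day 6, 3774 higher and 3472 lower, with 680 at least 2-fold higher and 530 at least 2-fold lower. Of the named genes, 2108 were higher and 2111 lower. The fit with extraction session as a block called 8235, and the Cy3 channel alone, an alternative chosen after seeing the data, called 4460.

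**Figure D2:**
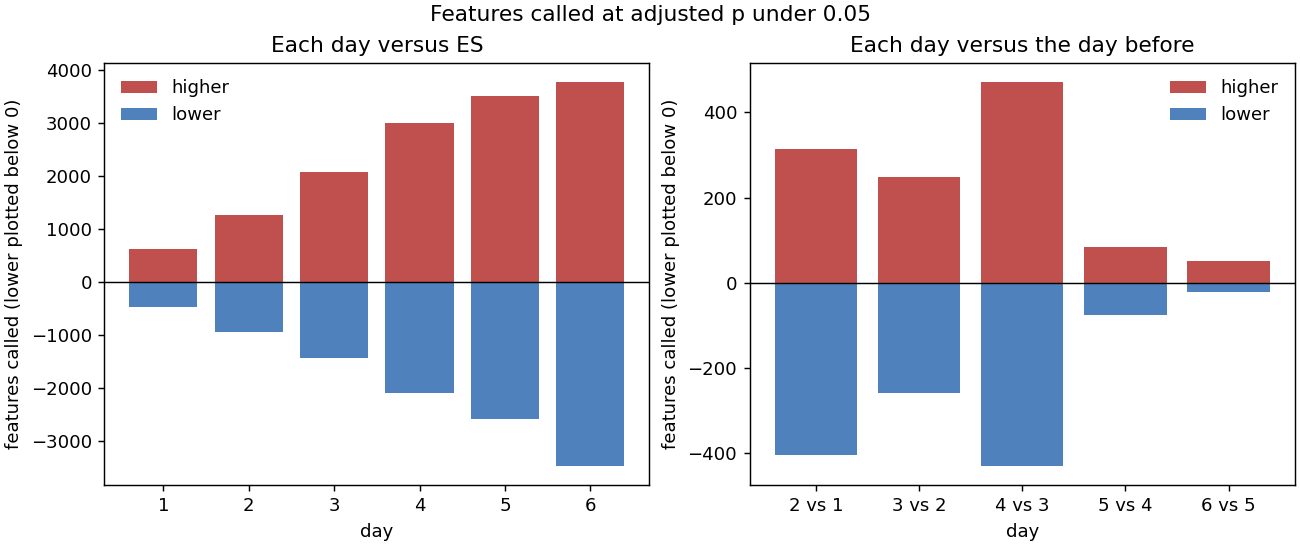
Bars give the number of features called higher (above 0) or lower (below 0) at adjusted p under 0.05, on the left for each day against ES and on the right for each day against the day before. The total rises from 1091 at day 1 to 7246 at day 6, while the daily steps hold 719, 509, 901, 160 and 73 features.

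All 14 measured genes of the naive pluripotency list were lower at day 6 than in ES (median -3.48, camera adjusted p = 1.12e-13). The median was -3.34 in extraction session 1 and -3.63 in session 2. The call held with an estimated correlation (adjusted p = 0.0220), but not when session was also a block (adjusted p = 0.0538). Tcl1, a co-activator of Akt, was at -3.49 ± 0.10. Dppa5a, saturated on both ES arrays, was 11.1-fold lower in the fitted ratio and at least 33.1-fold lower in its Cy3 signal. Of 14 measured general pluripotency genes, 13 fell and 1 was not called (median -1.48, adjusted p = 1.29e-08), with an adjusted p = 0.0712 with an estimated correlation. Pou5f1 (Oct4), the core pluripotency factor, fell 7.36-fold, Lefty1, a Nodal antagonist, 12.0-fold, and Dppa4 11.6-fold. Sox2, which is expressed in ES cells and in neural progenitors, was lower by a smaller amount (-0.80 ± 0.17), a call lost on Agilent's processed ratios (-0.51, adjusted p = 0.181) and in the series matrix. Of 10 measured LIF STAT3 targets, genes that LIF induces in ES cells, 9 fell (adjusted p = 5.57e-07, and 0.0159 with an estimated correlation). Klf4 was at -3.01 ± 0.21, the kinase gene Pim3 at -2.67 ± 0.10 and Socs3, the feedback inhibitor of the pathway, at -1.31 ± 0.13. Klf4 and Klf5 stand in this list and in the naive list. Nanog was not named here.

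Of 26 measured neural progenitor genes, 18 rose, 1 fell and 7 were not called (median 1.06, camera adjusted p = 2.41e-09). The call held with an estimated correlation (adjusted p = 0.00571), and the median was 1.06 in extraction session 1 and 1.22 in session 2. Cdh2 (N-cadherin), the cadherin of the neural plate, rose 9.24-fold (3.21 ± 0.14) while Cdh1 (E-cadherin) fell 5.28-fold (-2.40 ± 0.14). Pax6, a determinant of neuroectoderm, was at 0.78 ± 0.16 (0.51 without day 6 replicate 2) and Nes, the intermediate filament of neural progenitors, at 0.71 ± 0.12, the latter not called in the Cy3 channel alone (0.54, adjusted p = 0.177). Sox1, the marker most used for neuroectoderm, was at -0.04 ± 0.07 (adjusted p = 0.680) and Sox3 at 0.00 ± 0.09 (adjusted p = 0.998). The probe of Sox1 was well above background on all 14 arrays and that of Sox3 on all except 1 of the 2 day 5 arrays. Of 15 measured Notch pathway genes, 9 rose and 6 were not called (adjusted p = 0.000350). With an estimated correlation the adjusted p = 0.0292, and with session also a block it was 0.0598. Besides Hes5, these included Nrarp, a feedback inhibitor of Notch (1.40 ± 0.09), the fringe gene Mfng (1.18 ± 0.08) and Hes6 (1.03 ± 0.08).

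Of 31 measured neuron genes, 16 rose, 4 fell and 11 were not called (median 0.25, adjusted p = 0.0137). That call was lost with an estimated correlation (adjusted p = 0.221). Nefm, a neurofilament subunit, rose 3.39-fold and Rtn1 2.93-fold. Tubb3 (neuronal class III tubulin) was at 0.73 ± 0.16 and Neurog2 at 0.58 ± 0.10, the latter not called in the Cy3 channel alone (0.67, adjusted p = 0.0937). Neurod1 fell (-1.18 ± 0.18), as did Stmn2 (-0.68 ± 0.10), and Map2, a dendritic protein, was at -0.09 ± 0.06 (adjusted p = 0.301). Of 13 measured glia genes 2 rose and 4 fell (adjusted p = 0.292), the latter including Apoe (-1.32 ± 0.13), and Olig2 was at -0.06 ± 0.09 (adjusted p = 0.686). Of 13 measured mature brain genes 4 rose and 1 fell (adjusted p = 0.140), led by Sst, the neuropeptide somatostatin (1.47 ± 0.08). Dcx and Gfap were not named here.

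Along the neural axis, 8 of 21 measured hindbrain and spinal cord patterning genes rose and 2 fell at day 6 (adjusted p = 0.0924). Besides Irx3, these included the hindbrain genes Hoxa2 (2.01 ± 0.16) and Egr2 (Krox20, 1.19 ± 0.33). The Egr2 call was lost without background subtraction (0.58, adjusted p = 0.0925), and without ES replicate 1 (0.91) or day 6 replicate 1 (1.07). The list itself was called in the Cy3 channel alone (adjusted p = 0.0270) and without day 6 replicate 1 (adjusted p = 0.00750). Of 16 measured forebrain and midbrain patterning genes 4 rose and 1 fell (adjusted p = 0.209). Lhx2 was at 0.92 ± 0.09 and Emx2, well above background on 1 of the 2 ES arrays, at 0.71 ± 0.12. En2, of the midbrain and anterior hindbrain, was at 1.18 ± 0.41, a call lost without background subtraction, on processed ratios, in the series matrix, with median centring, with a trended robust variance, and without any array of ES or of days 1, 2, 3 or 6 (0.86 to 1.27). Of 12 measured neural crest genes 5 rose and 1 fell (adjusted p = 0.0347), with an adjusted p = 0.221 with an estimated correlation. The list was not called without background subtraction (adjusted p = 0.0575), on processed ratios (0.0521), with median centring (0.0605) or in the series matrix (0.0623). Tfap2b rose 13.5-fold and Pax3 3.21-fold, whereas Foxd3, a gene of ES cells as well as crest, fell 3.99-fold. Hoxb1 was not named here.

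Among signalling and metabolic lists at day 6, 9 of 15 measured cholesterol synthesis genes rose and 1 fell (adjusted p = 0.000406), with an adjusted p = 0.172 with an estimated correlation. Sc5d was at 1.08 ± 0.09 and Msmo1 at 0.87 ± 0.12. Of 10 measured FGF ERK targets 7 fell and 1 rose (adjusted p = 0.0142), with an adjusted p = 0.221 with an estimated correlation, and Etv5, an ETS factor induced by FGF signalling, was at -2.80 ± 0.15. Of 20 measured S, G2 and M phase genes 9 fell (adjusted p = 0.0175), with an adjusted p = 0.341 with an estimated correlation. Ccne1 (cyclin E1) was at -1.32 ± 0.10 and Cdc20, an activator of the anaphase-promoting complex, at -0.92 ± 0.10. Of 14 measured cyclin D and CDK inhibitor genes 5 rose (adjusted p = 0.0314), with an adjusted p = 0.370 with an estimated correlation, among them Cdkn1a (p21) at 1.29 ± 0.08. That list was not called on processed ratios (adjusted p = 0.0603) or in the series matrix (0.0623). Of 13 measured germline genes 9 fell (adjusted p = 4.18e-06), with an adjusted p = 0.0564 with an estimated correlation. Dnmt3l, a cofactor of de novo DNA methylation, was at -3.06 ± 0.11, its Cy5 signal having fallen by 1.43 on the log2 scale, and Rhox5 was at -2.46 ± 0.13.

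The other signalling and metabolic lists were not called at day 6. Of 9 measured BMP SMAD targets 4 rose and 1 fell (adjusted p = 0.243), Id3, an inhibitor of differentiation induced by BMP, being at 1.45 ± 0.20. Of 10 measured Wnt targets 3 rose (adjusted p = 0.100), led by Nkd1 (2.88 ± 0.23). Fitted on the ES and day 6 arrays alone, the Wnt list was called (adjusted p = 0.0352). Of 17 measured glycolysis and hypoxia genes 4 rose and 4 fell (adjusted p = 0.377), the latter including the hexokinase gene Hk2 (-1.52 ± 0.17) and Pfkp (-1.89 ± 0.18). Of 16 measured amino acid and ER stress genes 6 rose and 3 fell (adjusted p = 0.340), of 11 measured p53 and apoptosis genes 3 rose and 5 fell (adjusted p = 0.857), and of 11 serum response genes 3 fell (adjusted p = 0.250). Of 14 measured cell adhesion genes 3 rose and 6 fell (adjusted p = 0.145), Epcam falling 8.79-fold and Cdh11 rising 4.64-fold. Of 12 measured primed epiblast genes 2 rose and 4 fell (adjusted p = 0.240). Sall2 was at 2.53 ± 0.11 and Dnmt3b, a de novo DNA methyltransferase, at -2.71 ± 0.22.

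Markers of other cell types that such cultures could hold were mostly not called as lists at day 6. Of 18 measured primitive streak and mesoderm genes 6 rose and 2 fell (adjusted p = 0.501). Foxc1 was at 1.38 ± 0.14 and T (brachyury) at 0.16 ± 0.10 (adjusted p = 0.232). In the Cy3 channel alone T was at -0.47 (limma adjusted p = 0.144). Tcf15 was at -2.80 ± 0.14, its Cy5 signal having fallen by 1.27 on the log2 scale. Mixl1 was at 0.21 ± 0.08, a call lost in 6 settings and without any array of ES, days 3 to 5 or day 6 replicate 1 (0.11 to 0.36). Of 17 measured endoderm genes 6 rose and 4 fell (adjusted p = 0.676), led by Cxcr4, a chemokine receptor also found on neural progenitors (2.55 ± 0.18), with Foxa2 at 0.93 ± 0.15, not called in the Cy3 channel alone (0.88), and Sox17 at 0.04 ± 0.07 (adjusted p = 0.736). Of 9 measured trophectoderm genes 1 rose and 2 fell (adjusted p = 0.0884), a list called without day 6 replicate 2 (adjusted p = 0.0430) and in the Cy3 channel alone (0.0481). Tfap2c was at -2.06 ± 0.14 and Cdx2 at 0.48 ± 0.12, the latter not called without day 6 replicate 2 (0.42) and at -0.01 in the Cy3 channel alone. Of 8 measured surface ectoderm genes 2 rose and 3 fell (adjusted p = 0.131), and the list was called lower in the Cy3 channel alone (adjusted p = 0.0318). Of 10 measured fibroblast genes 4 rose and 1 fell (adjusted p = 0.116), a list called higher when fitted on the ES and day 6 arrays alone (adjusted p = 0.0352). Postn, well above background on 1 of the 2 ES arrays, was at 1.93 ± 0.15 and Col1a1 at 0.31 ± 0.19 (adjusted p = 0.225). Of 11 blood and endothelium genes 1 rose and 2 fell (adjusted p = 0.805), and of 9 cardiac muscle genes 2 rose and 4 fell (adjusted p = 0.340). Gata4, Gata6 and Id1 were not named here.

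Adjusted over the list alone, the day 6 counts were the same as those over all genes for 21 of the 31 lists. The other 10 each gained 1 to 3 members. Over the list alone, 5 primed epiblast, 3 trophectoderm, 10 LIF STAT3, 8 FGF ERK, 10 germline and 7 cell adhesion genes fell. The Notch list gained 1 gene that fell, the mesoderm list had 4 that fell, the amino acid and ER stress list had 7 that rose, and the glycolysis list had 6 that rose and 5 that fell.

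**Figure D3:**
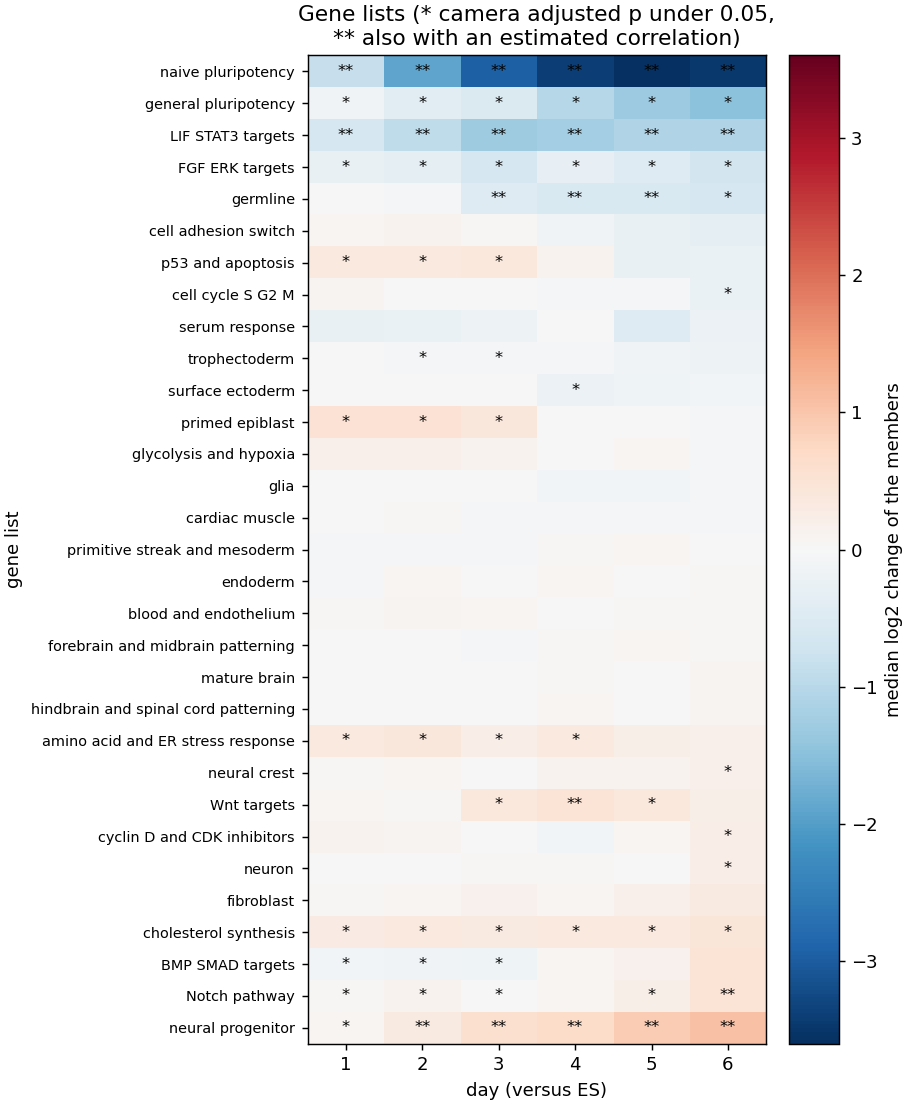
Colour gives the median log2 change against ES of the measured members of each of 31 gene lists (rows) on days 1 to 6 (columns), on a scale from blue (lower) to red (higher); a star marks a camera adjusted p under 0.05 and 2 stars one that held with an estimated correlation. The naive pluripotency list goes from -0.83 at day 1 to -3.48 at day 6, and the neural progenitor list from 0.06 to 1.06.

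Day 1 against ES asked what changed within a day of the change to N2B27. Klf4 fell 6.64-fold (-2.73 ± 0.21, adjusted p = 3.30e-05) and Socs3 6.49-fold (-2.70 ± 0.13), followed by Jam2 (-2.17 ± 0.12), Tcl1 (-1.87 ± 0.10) and Hbegf, an EGF receptor ligand (-1.76 ± 0.15). Sall2, a zinc finger gene, rose 4.03-fold (2.01 ± 0.11) and Hes6 3.39-fold, followed by Ddit4, an inhibitor of mTOR signalling (1.68 ± 0.14), Gadd45g (1.51 ± 0.23) and Cnksr3 (1.44 ± 0.12). Of the 14 measured naive pluripotency genes 8 fell (adjusted p = 2.22e-16, 0.0199 with an estimated correlation), as did 6 of 10 LIF STAT3 targets (adjusted p = 1.50e-13, 0.00348 with an estimated correlation). Pou5f1 was at 0.12 ± 0.23 (adjusted p = 0.914). Of 12 measured primed epiblast genes 6 rose (adjusted p = 2.53e-07), with an adjusted p = 0.114 with an estimated correlation. Fgf5, the marker of post-implantation epiblast, was at 0.45 ± 0.07, and Otx2 at 0.66 ± 0.22 was not called (adjusted p = 0.131). Adjusted over the list alone, 11 naive genes and 6 LIF STAT3 targets fell, and 7 primed epiblast genes rose and 1 fell.

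At day 1, 5 of 16 amino acid and ER stress genes rose (adjusted p = 4.34e-08), as did 5 of 11 p53 and apoptosis genes (adjusted p = 2.92e-06) and 6 of 15 cholesterol synthesis genes (adjusted p = 1.09e-05). With an estimated correlation these had adjusted p = 0.111, 0.0556 and 0.0927, and the p53 list 0.0375 with session also a block. Of 9 BMP SMAD targets 2 fell (adjusted p = 0.000837, 0.0556 with an estimated correlation), among them Id3 (-1.17 ± 0.20). When adjusted over the list alone, 8 amino acid and ER stress, 6 p53 and 12 cholesterol synthesis genes rose and 3 BMP SMAD targets fell. The features called numbered 1091, 613 higher and 478 lower, with 28 and 60 at least 2-fold. Session as a block gave 1805, median centring 454, the ES and day 1 arrays alone 622, and the Cy3 channel alone 560. Without ES replicate 1, ES replicate 2 or day 1 replicate 1 the count was 505, 507 and 538.

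By day 2 several falls had deepened. Jam2 was 14.2-fold lower than in ES (-3.83 ± 0.12, adjusted p = 1.34e-08), Tcl1 9.02-fold, Nr0b1 7.61-fold and Morc1 7.11-fold. Irx3 was 5.10-fold higher, Pdzrn3 4.80-fold, Herpud1, of ER-associated degradation, 4.54-fold, and Meis2 4.16-fold. Of 26 neural progenitor genes 11 rose (adjusted p = 2.08e-07, 0.00446 with an estimated correlation), among them Fabp7 (1.34 ± 0.21), and 11 of 14 naive genes fell (adjusted p = 2.88e-24, 0.00446 with an estimated correlation). Over the list alone, 12 neural progenitor genes rose and 13 naive genes fell. Fgf5 reached 0.80 ± 0.07. The count was 2214, 1259 higher and 955 lower, against 2983 with session as a block. It was 1149 with median centring, 1210 in the Cy3 channel alone, and 1232, 1248 and 1295 without ES replicate 1, ES replicate 2 or day 2 replicate 1.

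At day 3, Irx3 was 17.7-fold higher than in ES (4.14 ± 0.13, adjusted p = 5.71e-09), Meis2 8.49-fold, and Wnt8a, a Wnt ligand of the caudal embryo, 5.72-fold. Pdzrn3 was at 2.95 ± 0.15 and Cxcl12, the ligand of Cxcr4, at 2.40 ± 0.23. Morc1 was 20.7-fold lower, Jam2 12.7-fold, Nr0b1 12.5-fold, Tcl1 11.1-fold and Ooep, an oocyte gene, 10.7-fold. Pou5f1 was still at -0.31 ± 0.23 (adjusted p = 0.479), and Cdh1 at 0.01 ± 0.14 (adjusted p = 0.977), while Cdh2 had risen (1.53 ± 0.14). Of 13 germline genes 7 fell (adjusted p = 8.21e-08, 0.0350 with an estimated correlation), but with session also a block the adjusted p = 0.0729. Of 10 Wnt targets 5 rose (adjusted p = 0.00223), with an adjusted p = 0.0545 with an estimated correlation, and T was at 0.45 ± 0.10. Over the list alone, 9 germline genes fell and 5 Wnt targets rose. The count was 3509, 2079 higher and 1430 lower, against 4299 with session as a block, 2272 with median centring and 2134 in the Cy3 channel alone.

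Day 4 was the first on which Pou5f1 and Cdh1 were called lower than in ES, at -1.66 ± 0.23 and -1.36 ± 0.14. Meis2 was 21.5-fold higher, Zfp521 18.2-fold, Irx3 17.7-fold, Sp8, a zinc finger gene of neural patterning, 11.2-fold and Nkd1, an antagonist of Wnt signalling, 9.86-fold. Zfp42 was 19.8-fold lower, Rpl39l 17.8-fold, Dppa3 15.0-fold and Nr0b1 14.6-fold. Morc1 was 33.7-fold lower in the fitted ratio and at least 39.5-fold lower in its Cy3 signal. All 14 naive pluripotency genes fell (adjusted p = 8.30e-19, 0.00887 with an estimated correlation). Of 26 neural progenitor genes 15 rose (adjusted p = 1.06e-08, 0.00742 with an estimated correlation), and of 10 Wnt targets 7 rose (adjusted p = 0.000670, 0.0340 with an estimated correlation). With session also a block the Wnt list had an adjusted p = 0.0578. These 3 counts were the same over the list alone. The count was 5101, 2996 higher and 2105 lower, against 6075 with session as a block and 3232 in the Cy3 channel alone.

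By day 5, Dnmt3b was called lower than in ES (-1.95 ± 0.22). Zfp521 was 21.7-fold higher, Insl6 20.5-fold, Meis2 20.3-fold, Apcdd1, an inhibitor of Wnt signalling, 18.0-fold and Rgs2 17.9-fold. Zfp42 was 26.3-fold lower, Klf2 21.8-fold, Tdgf1 20.1-fold and Rpl39l 18.1-fold. Morc1 was 36.1-fold lower in the fitted ratio and at least 40.9-fold lower in its Cy3 signal. Of 26 neural progenitor genes 16 rose and 1 fell (adjusted p = 2.02e-08, 0.00851 with an estimated correlation), and over the list alone 17 rose and 1 fell. The count was 6116, 3521 higher and 2595 lower, against 7058 with session as a block and 3632 in the Cy3 channel alone. Over the 31 lists, camera called 11, 12, 14, 10, 9 and 12 on days 1 to 6, of which 2, 3, 4, 5, 4 and 4 held with an estimated correlation. With session also a block and an estimated correlation, 3 were called on each of days 1 to 5 and 2 on day 6, and the germline list was then not called on day 4 (adjusted p = 0.0578) or day 5 (0.0789).

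**Figure D4:**
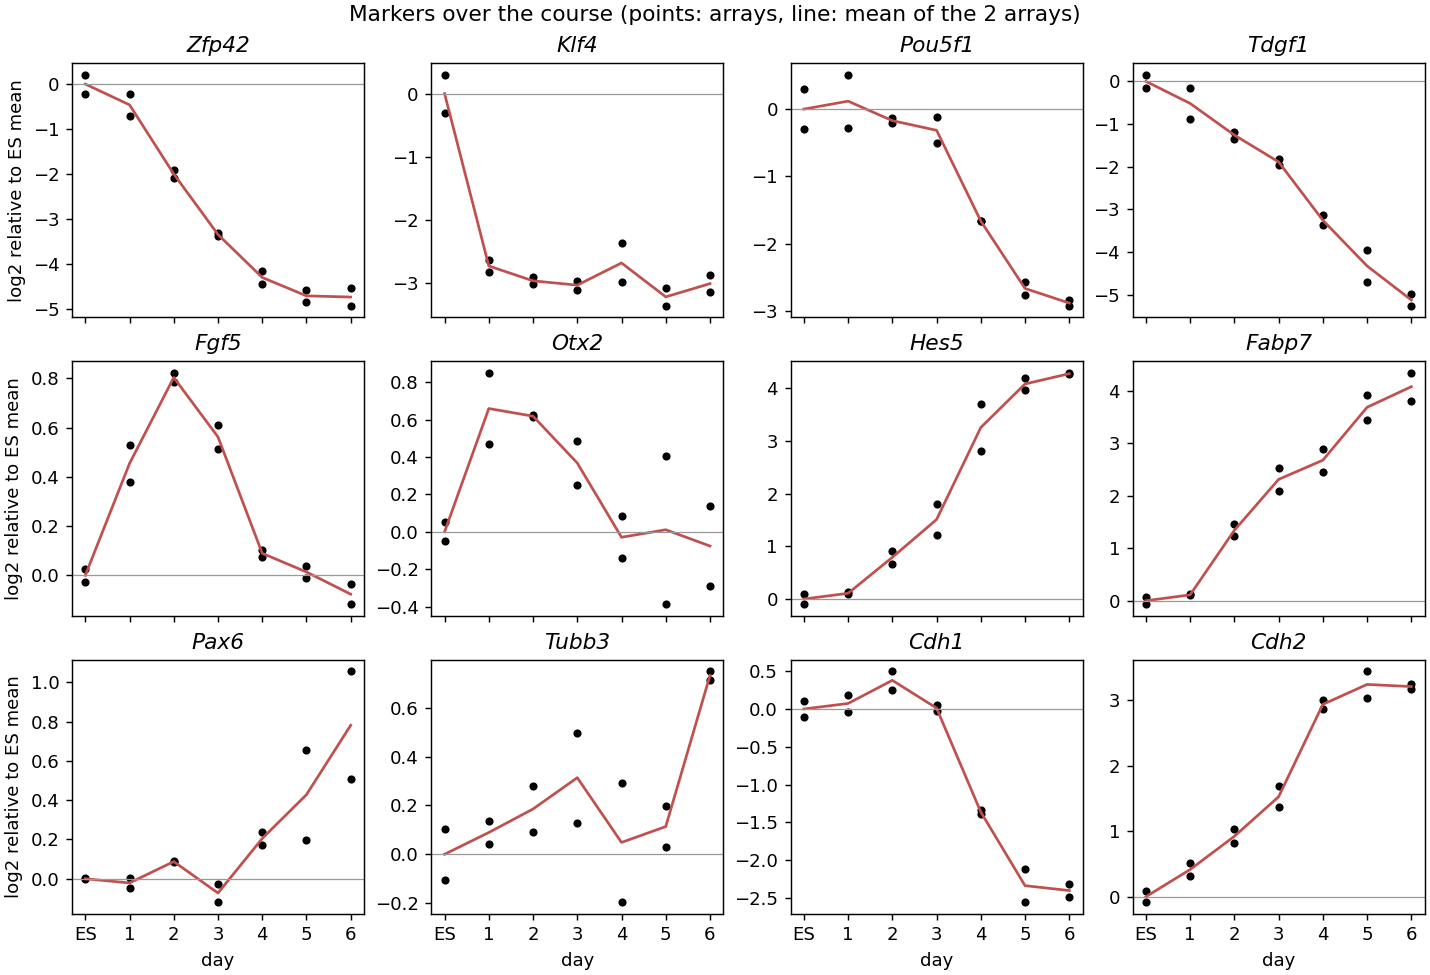
Each panel plots the log2 ratio of a gene relative to the mean of the ES arrays (vertical axis, scaled per panel) by day (horizontal axis), with a point per array and a line through the mean of the 2 arrays. Klf4 reaches -2.73 by day 1 and Zfp42 -4.74 by day 6, Pou5f1 is at -0.31 on day 3 and -2.88 on day 6, and Fgf5 is highest on day 2 (0.80).

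The daily steps asked when along the course expression changed. From day 1 to day 2, Atf3, a stress-responsive transcription factor, rose by 1.34 ± 0.13 (adjusted p = 0.000192), Pdzrn3 by 1.33 ± 0.15 and Fabp7 by 1.23 ± 0.21. Nr0b1 changed by -1.97 ± 0.11, Morc1 by -1.78 ± 0.09 and Jam2 by -1.66 ± 0.12. This step held 719 features, 313 higher and 406 lower, and 1239 with session as a block. Its count was 416 on processed ratios, 357 with median centring, 446 in the series matrix, 367 on the 4 arrays alone and 295 in the Cy3 channel alone, and 456, 276 and 421 without day 1 replicate 1, day 2 replicate 1 or day 2 replicate 2.

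From day 2 to day 3, Sp5, a Wnt target, rose by 2.09 ± 0.32 (adjusted p = 0.00482), Irx3 by 1.79 ± 0.13 and Ntn1, the axon guidance cue netrin 1, by 1.74 ± 0.19. Tcf15 changed by -1.86 ± 0.14, Dppa5a by -1.77 ± 0.26 and Rpl39l by -1.65 ± 0.16. This step held 509 features, 249 higher and 260 lower, and 831 with session as a block. Its count was 267 on processed ratios, 186 with median centring, 278 in the series matrix, 302 on the 4 arrays alone and 177 in the Cy3 channel alone. Without day 2 replicate 1, day 2 replicate 2, day 3 replicate 1 or day 3 replicate 2 it was 210, 196, 208 and 203.

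From day 3 to day 4, Egr2 rose by 3.05 ± 0.33 (adjusted p = 0.000308), Apcdd1 by 2.18 ± 0.29 and Pla2g7, a secreted phospholipase, by 2.07 ± 0.22. Slc27a2, a fatty acid transporter, changed by -2.00 ± 0.17, Epcam by -1.94 ± 0.11 and Cxcl12 by -1.74 ± 0.23. This step held 901 features, 471 higher and 430 lower, and 1457 with session as a block. Its count was 589 on processed ratios, 397 with median centring, 360 on the 4 arrays alone and 345 in the Cy3 channel alone. Without day 3 replicate 1, day 3 replicate 2, day 4 replicate 1 or day 4 replicate 2 it was 511, 403, 598 and 543.

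From day 4 to day 5, Tfap2b rose by 1.73 ± 0.11 (adjusted p = 0.000136), Zic1 by 1.61 ± 0.19 and Igfbp5 by 1.36 ± 0.12. Wnt8a changed by -1.38 ± 0.14, Dnmt3b by -1.35 ± 0.22 and Pla2g7 by -1.32 ± 0.22. This step held 160 features, 84 higher and 76 lower, and 357 with session as a block. Its count was 48 on processed ratios, 36 with median centring, 47 in the series matrix, 13 on the 4 arrays alone and 55 in the Cy3 channel alone. It was 103 without either ES array, 93 and 81 without day 4 replicate 1 or 2, and 104 and 35 without day 5 replicate 1 or 2.

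From day 5 to day 6, Tfap2b rose by a further 1.29 ± 0.11 (adjusted p = 0.000768), Nefm by 1.12 ± 0.12 and Sst by 1.10 ± 0.08. Wnt8a changed by -1.36 ± 0.14, Trh, the thyrotropin-releasing hormone precursor, by -1.19 ± 0.15 and Lratd1 by -1.01 ± 0.14. This step held 73 features, 50 higher and 23 lower, and 253 with session as a block. Its count was 31 on processed ratios, 20 with median centring, 24 in the series matrix, 36 on the 4 arrays alone and 16 in the Cy3 channel alone. Without day 5 replicate 1, day 5 replicate 2 or day 6 replicate 1 it was 30, 28 and 36.

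Transient genes were those higher on days 2 and 3 than in ES and than on days 5 and 6. By the smaller of the 2 differences, the 10 leading genes were Rapgef5, Cxcl12, Chst1, Calcr, Tmem145, Zmynd8, Nme3, Galnt3, Cnksr3 and Pou3f3. Rapgef5, an exchange factor for Rap proteins, was 1.77 ± 0.08 above ES and 2.02 ± 0.07 above the late days (adjusted p = 6.65e-08 and 4.06e-09). Cxcl12 was 2.18 ± 0.20 and 1.60 ± 0.16 above them, and Pou3f3, a POU factor of neural progenitors, 1.08 ± 0.11 and 1.40 ± 0.09. In all 442 features met both conditions, 271 of them named genes, and 181 had the opposite course. The count was 597 with session as a block, 216 with median centring, 285 in the Cy3 channel alone, and 257 and 255 without ES replicate 1 or 2.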

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

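The tests of the Cy5 channel and of the daily steps were written down before their results, and the test of the Sox1 probe after. The pairs of days below were chosen after their values were seen, as the pair with the widest difference for each gene.

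Among the genes picked by the rule for named genes and reported here, 16 were called in opposite directions against ES on 2 days. The difference between those days was called in each as well, which adds nothing, since the genes and days were picked for it. Among genes higher early and lower late, Slc27a2 changed by -4.10 from day 2 to day 6, Foxd3 by -2.66 and Neurod1 by -2.48 from day 1 to day 5, and Gadd45g by -2.41 from day 1 to day 4. From day 2 to day 6 Pmaip1 changed by -2.34 and Cebpb by -2.07, and from day 3 to day 6 Rapgef5 changed by -2.14 and Calcr by -2.10. Pou3f3 (-1.97) and Galnt3 (-1.77) changed from day 2 to day 5. Among genes lower early and higher late, Ntn1 and Sp5 changed by 3.48 each from day 2 to day 4, Id3 by 2.81 and Cdkn1c by 1.18 from day 2 to day 6, and Phlda1 by 1.79 and Tagln by 1.27 from day 1 to day 6. The late calls of Rapgef5, Calcr, Phlda1 and Tagln were lost at day 6 both without ES replicate 2 (-0.31, -0.42, 0.31 and 0.44) and without day 6 replicate 1 (-0.28, -0.46, 0.52 and 0.50). That of Rapgef5 was also lost without background subtraction (-0.09) and on processed ratios (-0.48), that of Calcr in the Cy3 channel alone (-0.27), that of Tagln with median centring (0.56) and that of Phlda1 without day 6 replicate 2 (0.53).

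Analysed alone at day 6 against ES, the Cy5 channel had 632 features at an unadjusted p under 0.05. Unchanged features alone would give no fewer. The channel held the same reference RNA on every array, yet 8 of its features were called. They were Tdgf1, Gdf3, Dnmt3l, Utf1, Tcf15, Tcea3 and 2 unnamed probes, of which Gdf3, Utf1 and Tcea3 fell outside the rule for named genes and were chosen after their values were seen. All 8 moved in Cy5 the way they moved in Cy3, as Tdgf1 did (-2.38 ± 0.18 in Cy5 and -7.13 in Cy3), and Cy3 signal read in the Cy5 channel may account for them. Quantile scaling of Cy5 is argued against, since 8 of the 8 were also called after median centring. Competition for the probe would move Cy5 the other way. No biological explanation was tested, since the channel held no sample.

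Fewer features changed from day 4 to 5 (160) and from day 5 to 6 (73) than from day 3 to 4 (901). Noisier late arrays could not lower the late counts alone, since the spread was pooled over all groups and the median SE was 0.081 in each of these steps. They were also argued against by the covariance of the replicates' changes, to which independent noise adds nothing. It was 0.391 times as large from day 4 to 5 as from day 3 to 4. For the loess step, the test written down was the count on Agilent's processed ratios, where the later count was 0.0815 times the earlier. Those ratios carry Agilent's own dye normalization, so that test alone does not decide. Median centring, which uses no loess, also gave far fewer features from day 4 to 5 than from day 3 to 4. That comparison was not written down beforehand, but it argues against the loess step. A slowing of the course itself, which the days of the design name, may remain as a hypothesis, and mixed or unequally timed cultures were not tested.

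Sox1 did not change while the neural progenitor list rose. The mean brightness of its probe over both channels lay above that of 52.8% of tested features. The probe was well above background in Cy3 on 14 arrays, so by the rule written for this test it was not dim. That does not decide whether its sample signal was too weak to report a change. Mean brightness includes the reference channel, and 95.8% to 98.9% of probes per array pass the Cy3 flag. A probe that binds another transcript, or a transcript variant that it misses, could give the same flat course and was not tested, and neither was an absence of Sox1 induction.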

How the results depend on the processing

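Across 364 combinations of a count and an alternative, 292 stayed within 1.5 times the reported count and 72 did not. Among the 292 are the Aquantile counts, which could not differ. Leaving out an array of a group not compared changes only the pooled spread of a contrast. The Cy3 channel alone was chosen after seeing the data. For counts that moved, the cause was not tested, except that fits with an array left out or on only the groups compared have fewer arrays. Where a group kept 1 array, that array was assumed to vary like the other groups. In the order of the steps from day 1 to 2 up to day 5 to 6, the counts were 416, 267, 589, 48 and 31 on Agilent's processed ratios and 357, 186, 397, 36 and 20 with median centring. Median centring also gave 454, 1149 and 2272 for days 1 to 3 against ES and 216 transient features. The series matrix gave 446 and 278 for the steps to days 2 and 3, and 47 and 24 for those to days 5 and 6. The replicate block gave 1805 at day 1 and 1239, 831, 1457, 357 and 253 in the steps, and it moved no other count by over 1.5 times. Fits on only the groups compared gave 622 at day 1 and 367, 302, 360, 13 and 36 in the steps; the F test was not run that way. The Cy3 channel alone gave 560, 1210, 2134, 3232, 3632 and 4460 for days 1 to 6, 295, 177, 345, 55 and 16 for the steps, 4398 at any time and 285 transient features. An estimated correlation left 4 of the 12 lists called at day 6, and 2 with the block as well.

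With each array left out in turn, the counts ran from 505 to 1297, 1232 to 2302, 2358 to 3610, 3611 to 5160, 4438 to 6172 and 5184 to 7245 for days 1 to 6. The steps ran from 276 to 746, 196 to 563, 403 to 935, 35 to 180 and 28 to 74, the F test from 6016 to 6951, transient features from 255 to 458 and lists from 12 to 13. The lowest count of the 6 days came without an ES array each time. The share of called features that rose at day 6 lay between 50.5% and 55.8% over all alternatives. Of the 183 named genes at day 6, 11 lost their call without background subtraction, 8 on processed ratios, 10 with median centring, 7 in the series matrix and 21 in the Cy3 channel alone. Without ES replicate 1 or 2, 12 of 183 and 17 of 181 lost it, without day 6 replicate 1 or 2 17 and 10, and without any other array at most 4. Of the 159 of these genes called at day 6, 82 had a log2 change over 1.5 times smaller without background subtraction, the most of any setting, and 18 one over 1.5 times larger on processed ratios. In the Cy3 channel alone 1 of these called genes, Cdx2, turned from 0.48 to -0.013. Some genes not called at day 6, such as T, changed sign there as well. Aquantile changed no count, since it leaves the ratios as they are. A block for the extraction session is the replicate block, and slides were not tested as a block. Samples of the same number did not deviate together throughout: the correlation of replicate differences between 2 groups ran from -0.06 to 0.60 and was over 0.1 in 17 of 21 pairs of groups. Since 4 pairs fell short, the numbers are not taken to pair the samples, but they do mark the extraction session, and most pairs of groups shared part of their replicate differences. The filter on signal removed few probes: 385 were untested, and 19427 were well above background in both channels on all arrays. That flag does not show whether a dim probe can report a change in full.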

Other observations

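The gene groups of this part, and the contrast of even with odd days, were chosen after values had been seen, and the genes named here fall partly outside the rule for named genes. The p-values of these groups are therefore no independent tests, and adjusting over the 6 groups does not correct for that choice. A first group held genes of epithelial junctions and other genes taken as epithelial. Of its 18 measured members 13 fell at day 6 and 2 rose (median -1.39, camera adjusted p = 1.92e-07 over 6 groups, 0.0106 with an estimated correlation). Besides Epcam and Cdh1, Bspry was at -2.86 ± 0.10, the adaptor gene Grb7 at -2.18 ± 0.12 and Spint2, an inhibitor of membrane serine proteases, at -2.13 ± 0.07. At day 3 the group was not called (adjusted p = 0.198). Of 21 measured ribosome biogenesis genes, 20 fell at day 6 and 1 was not called (median -0.88, adjusted p = 4.47e-11, 0.0106 with an estimated correlation). Bop1 was at -1.43 ± 0.09, Polr1b, a subunit of RNA polymerase I, at -1.32 ± 0.09, and Npm1, which was not called, at 0.12 ± 0.16. At day 3, 9 of them fell (adjusted p = 0.000918), with an adjusted p = 0.290 with an estimated correlation. Both groups were lower at day 6 in each of 5 other scalings of the same arrays, from -0.75 to -1.50 and from -0.77 to -0.93 in their medians.

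Of 10 tested genes of the response to metals and oxidants, 7 fell at day 6 (adjusted p = 0.00182, 0.0293 with an estimated correlation). The metallothionein gene Mt1 was at -1.93 ± 0.24 and the zinc exporter gene Slc30a1 at -1.49 ± 0.14. Of 18 measured imprinted genes 9 rose and 2 fell (adjusted p = 0.00398), with an adjusted p = 0.0659 with an estimated correlation. Peg12 was at 2.95 ± 0.08 and Nnat at 1.57 ± 0.18, and the 2 that fell were Phlda2 (-2.65 ± 0.13) and Snrpn (-1.02 ± 0.17). Of 10 heat shock genes 6 fell and 1 rose (adjusted p = 0.00217), with an adjusted p = 0.230 with an estimated correlation, Hspb1 being at -2.68 ± 0.14. Of 12 retinoid genes 3 rose and 3 fell (adjusted p = 0.913), although Crabp1 among them rose 25.7-fold.

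Atf3 was at 0.19 ± 0.13, 1.53 ± 0.13, 0.56 ± 0.13, 1.77 ± 0.13, 0.70 ± 0.13 and 0.91 ± 0.13 against ES on days 1 to 6, so that days 2 and 4 stood above their neighbours and day 6 was close to day 5. A contrast of days 2 and 4 with days 1, 3 and 5, chosen after this course was seen and leaving day 6 out, was therefore no independent test of it. In that contrast 921 of 20393 features had an unadjusted p under 0.05, no more than unchanged features alone would give. With session as a block 10 were called, and without it limma called 2. Besides Atf3 (1.14 ± 0.08) this was Slc30a1 (0.82 ± 0.09), whose values on days 1 to 6 were -0.59, 0.44, -0.80, -0.57, -1.37 and -1.49. Of these the value of day 2 (± 0.14, adjusted p = 0.0744) was not called, and the others were called lower than ES. When the cells were fed or the medium changed is not given in the sources used here.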
